A study of Mus musculus with 24 samples.

How the data were processed

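Lung RNA of 24 mice was measured on 1-colour Affymetrix arrays after biotin labelling of 2 ug total RNA, per the labels' protocols. The 24 arrays fall into 8 groups of 3 by sample title, and the series design gives 3 mice per group. The deposited values are intensity values per probe set, normalized between arrays with RMA (Robust Multi-array Average), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. RMA usually returns log2 values, but the deposited intensity values ran from 5.98 to 18195.5 with array medians of 72.2 to 75.5, so they lie on a linear scale. The plan fixed before the data were examined took them to be log2, so log2 was taken first and the planned test was used otherwise as written. Spot background was not analysed here, so levels near or below the 25th percentile of an array are not shown to lie above background, and RMA tends to compress differences of dim probe sets.

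Of 22690 probe sets, 64 were Affymetrix controls, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Probe sets with several symbols or none were not named. For 4956 genes with several probe sets the one with the highest mean over all arrays was used, which left 12393 genes. No symbol was updated, and the identifiers of 12369 genes stood in the reference gene table. No filter on dim probe sets was applied. No column of per-sample values was left unused.

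limma 3.58.1 in R 4.3.3 fitted 1 linear model with 8 group means to all 24 arrays, with 16 residual degrees of freedom and 8.16 prior degrees of freedom. Moderated tests used eBayes without trend and were two-sided. P-values were adjusted by Benjamini-Hochberg within each of 17 comparisons at an adjusted p of 0.05. The comparisons were each particle against saline, OVA against saline, each particle with OVA against OVA, OVA averaged over the 4 backgrounds, each particle by OVA interaction, and the particles against each other with and without OVA. 42 gene lists with 648 members, of which 566 were measured, were fixed from textbook knowledge before the data were examined, and were tested with camera at an inter-gene correlation of 0.01 and adjusted over the lists. Camera was repeated with an estimated correlation. Correlations of fold changes between particles were set beside simulated unchanged groups that share the same control arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

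The genes named follow a rule fixed before the data were examined. For the comparisons with saline or OVA alone, it takes the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose arrays do not overlap, and for the averaged OVA effect those with the same sign in all 4 backgrounds. It adds up to 4 members with the smallest p of each list described. It takes 5 highest and 5 lowest for interactions and direct comparisons, and the 3 smallest p where no gene passed. 16 genes are always given: Cyp1a1, Cyp1b1, Hmox1, Nqo1, Cxcl1, Ccl2, Saa3, S100a8, Muc5ac, Clca1, Retnla, Ccl11, Il13, Il5, Epx and Chil4. By chance 10% of genes have no overlap between 3 and 3 arrays.

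The scripts were tested on simulated data with 12393 genes, 200 of them changed, in 10 simulations. For CDEP against saline, 84.0% of genes changed 1.5-fold, 99.4% changed 2-fold and 100% changed 4-fold were found, and 4.18% of calls were false. For the CDEP by OVA interaction the shares were 37.6%, 94.0% and 100%, with 4.83% false. For the averaged OVA effect they were 99.3%, 99.9% and 100%, with 3.98% false. Camera found a shifted list in 100% of simulations and called 0.488% of other lists. The simulated genes varied independently, unlike genes of a list that move together. These shares therefore do not show how often camera calls unchanged lists in the real data.

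Arrays were checked for copies. The highest correlation of any pair was 0.996 and the highest share of identical values in any pair was 0.0353%, so all 24 counted as separate. RNA quality was read from the difference between 3' and 5' control probe sets of Gapdh and Actb. Alternatives planned before the data were examined were all probe sets, a filter that kept 10387 genes above the 25th percentile on at least 3 arrays, quantile normalization again, array weights, a trended robust variance, only the compared groups in the fit, the replicate number as a block, and leaving out each array. Added after seeing the data were heart and fat list scores as covariates, the RNA quality differences as covariates, a fit without the 2 arrays of highest Gapdh difference, the gene list test with each array left out, and fits in which no control array served 2 particles.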

Results

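Gene expression was measured in the lungs of 24 female BALB/C mice, an inbred laboratory strain, with 1 Affymetrix array per mouse. The mice were 8 to 10 weeks old and formed 8 groups of 3. Saline was the control, and 20 ug ovalbumin (OVA), an egg white protein widely used as a model allergen, was given alone to 1 group. 3 groups received 150 ug of diesel exhaust particles (DEP), a soot sample from engine exhaust, and 3 groups received particles together with OVA. The particles are labelled N-DEP, A-DEP and C-DEP and are written NDEP, ADEP and CDEP here, and the series title calls them chemically distinct. Doses were placed in the nose on days 0 and 13, and tissue was taken 18 hours later. The comparisons ask how the lung responds to each particle, to OVA, and to both together. Array medians lay between 72.2 and 75.5 intensity units after normalization, which brings arrays to a common scale. The number of arrays per group limits the precision. Genes called dim in a group have a mean there below the 25th percentile of each of its arrays (4.45 to 4.64 log2 over all arrays), so they are not shown to lie above background there, and the size of their changes is uncertain. Log2 fold changes are followed by their SE, and levels are log2 intensities with SD, with n = 3 mice per group. Adjusted p-values come from limma unless camera is named. In comparisons with saline or OVA alone, the genes listed as highest or lowest passed an adjusted p of 0.05 and had no overlap between the arrays of both groups.

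**Figure D1:**
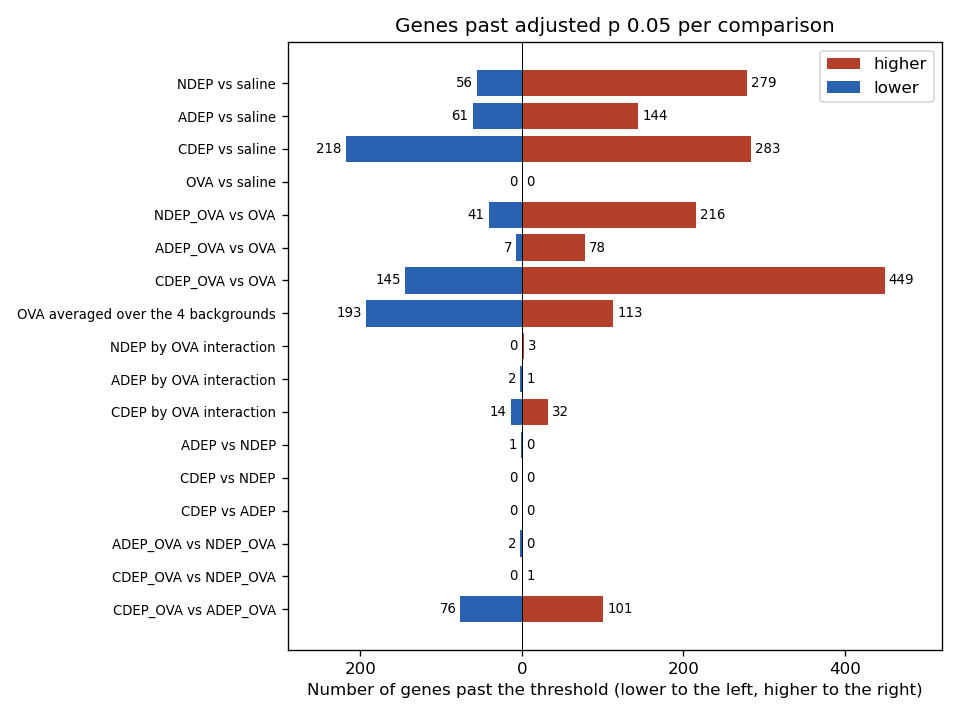
Number of genes with an adjusted p below 0.05 in each of the 17 comparisons, among 12393 genes, with higher genes to the right and lower genes to the left of 0. CDEP_OVA against OVA has 449 higher and 145 lower, and OVA against saline has 0.

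NDEP alone was followed by higher expression of acute phase, cytokine and neutrophil chemokine genes. Compared with saline, 279 genes were higher and 56 lower, 56 and 3 of them by at least 2-fold. The plasma acute phase protein Orm1 (Entrez gene 18405) rose 7.99-fold, from 4.84 ± 0.08 to 7.84 ± 0.35 log2 intensity (adjusted p = 6.41e-05). Saa3, a serum amyloid A made in inflamed tissue (Entrez gene 20210), rose by 2.61 ± 0.49 log2 and Lcn2, which withholds iron from bacteria, by 2.45 ± 0.36. Cd177, a neutrophil surface protein, rose by 2.57 ± 0.41, and the neutrophil chemokines Cxcl1 (Entrez gene 14825) and Cxcl5 by 2.38 ± 0.33 and 2.01 ± 0.33. Other genes among the 10 with the highest fold changes were the anion exchanger Slc26a4 (2.42 ± 0.29), Vnn1 (2.06 ± 0.18), the protease inhibitor Timp1 (1.88 ± 0.35) and Itih4 (1.87 ± 0.23). The 10 lowest were Nppa, the atrial natriuretic peptide of heart muscle (-1.66 ± 0.43), the drug-metabolising Cyp2e1 (-1.25 ± 0.29), Acaa1b (-1.13 ± 0.24), Scara5 (-0.92 ± 0.20), Lncpint (-0.90 ± 0.20), the pericyte gene Rgs5 (-0.80 ± 0.14), Prkg2 (-0.78 ± 0.19), Abca8a (-0.78 ± 0.20), Peg3 (-0.77 ± 0.18) and the clock gene Arntl (-0.76 ± 0.14). Lncpint was dim in NDEP. Of these 20 genes 12 passed with any 1 array left out. Nppa, Cyp2e1, Acaa1b, Scara5, Lncpint, Prkg2, Abca8a and Peg3 lost their call without 1 or more of saline replicates 1 and 3 and NDEP replicates 1, 2 and 3.

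Among the lists fixed in advance, acute phase and innate defence proteins were called after NDEP: 10 of 15 measured members rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 3.10e-19, adjusted p = 0.0378 with an estimated correlation). In the acute cytokine and neutrophil chemokine list, 7 of 16 measured members rose and 0 fell, 10 and 0 adjusted over the list alone (camera adjusted p = 7.77e-11, adjusted p = 0.0401 with an estimated correlation), with Csf2 at 1.27 ± 0.13 and Ccl3 at 1.56 ± 0.23. For complement components, 5 rose and 0 fell of 7, 5 and 0 adjusted over the list alone (camera adjusted p = 2.77e-09, adjusted p = 0.0216 with an estimated correlation), led by C1qb (1.13 ± 0.16) and Cfb (1.70 ± 0.25). NF-kB pathway genes followed, with Nfkbiz at 0.81 ± 0.12: 6 rose and 0 fell of 15, 11 and 0 adjusted over the list alone (camera adjusted p = 7.77e-11, adjusted p = 0.0216 with an estimated correlation). These 4 lists kept their call with an estimated correlation, and the other 18 of 22 called lists lost it. Neutrophil markers were one of those: 6 rose and 0 fell of 19, 9 and 0 adjusted over the list alone (camera adjusted p = 6.26e-07, adjusted p = 0.0815 with an estimated correlation), with Clec4d (1.35 ± 0.17) and S100a8 (1.43 ± 0.28). Monocyte chemokines included Ccl2 at 0.97 ± 0.22: 5 rose and 0 fell of 8, 7 and 0 adjusted over the list alone (camera adjusted p = 9.37e-07, adjusted p = 0.0773 with an estimated correlation). Among monocyte markers, 3 rose and 0 fell of 10, 5 and 0 adjusted over the list alone (camera adjusted p = 1.00e-05, adjusted p = 0.0505 with an estimated correlation), with Chil1 at 1.45 ± 0.21. Alveolar type 2 cell genes included the alarmin Il33 (1.66 ± 0.22) and surfactant protein Sftpd (0.96 ± 0.14): 5 rose and 0 fell of 13, 8 and 0 adjusted over the list alone (camera adjusted p = 9.51e-10, adjusted p = 0.0815 with an estimated correlation). In the MHC class II list, with Cd74 at 0.66 ± 0.13, 6 rose and 0 fell of 9, 7 and 0 adjusted over the list alone (camera adjusted p = 3.39e-08, adjusted p = 0.0809 with an estimated correlation). Ccl2 and Cd74 did not pass without saline replicate 1, and Ccl2 also not without NDEP replicate 3.

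Of the aryl hydrocarbon receptor targets, Cyp1b1 rose after NDEP by 1.17 ± 0.22 (adjusted p = 0.00326), and Cyp1a1 stood at 0.18 ± 0.26 (adjusted p = 0.808). In that list 1 rose and 0 fell of 7, 1 and 0 adjusted over the list alone (camera adjusted p = 0.111, adjusted p = 0.183 with an estimated correlation). Hmox1, a heme-degrading enzyme of the oxidative stress response, rose by 0.82 ± 0.16, while Nqo1 stood at -0.04 ± 0.14 (adjusted p = 0.930): in the NRF2 list, 1 rose and 0 fell of 16, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0571, adjusted p = 0.151 with an estimated correlation). Clock genes went both ways, with Bhlhe40 at 0.93 ± 0.11, Nr1d1 at 1.01 ± 0.21 and Clock at -0.50 ± 0.10: 3 rose and 2 fell of 16, 3 and 2 adjusted over the list alone (camera adjusted p = 0.432, adjusted p = 0.671 with an estimated correlation). None of Muc5ac (0.27 ± 0.18), Clca1 (-0.12 ± 0.90), Retnla (1.06 ± 0.44), Ccl11 (0.01 ± 0.14), Il13 (-0.08 ± 0.10), Il5 (-0.11 ± 0.12), Epx (0.04 ± 0.11) and Chil4 (-0.09 ± 0.27) passed the test. Heart muscle genes were lower as a list, median -0.32: 0 rose and 1 fell of 20, 0 and 2 adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.290 with an estimated correlation). Fat genes were lower likewise, median -0.31: 0 rose and 1 fell of 10, 0 and 2 adjusted over the list alone (camera adjusted p = 0.000399, adjusted p = 0.139 with an estimated correlation). The heart median was -0.09 without saline replicate 3, where the list and Nppa lost their calls, -0.18 without NDEP replicate 1 and -0.51 without NDEP replicate 3. Camera called the receptor targets without saline replicate 1 or NDEP replicate 1, and the NRF2 list without NDEP replicate 2. With saline replicate 1 left out Hmox1 and Nr1d1 lost their call and 152 genes passed, and without NDEP replicate 3 165. The count was 166 with heart and fat scores as covariates and 126 with RNA quality covariates, where the median size of the 335 changes went from 0.607 to 0.526 log2, the median SE from 0.134 to 0.143, and all 335 kept their sign.

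After ADEP alone 144 genes were higher and 61 lower than in saline. Orm1 rose 8.14-fold, to 7.86 ± 0.75 (adjusted p = 0.000435), and Saa3 by 2.60 ± 0.49 log2. Next came Timp1 (2.15 ± 0.35), Lcn2 (2.00 ± 0.36), Cd177 (1.93 ± 0.41), Cxcl1 (1.91 ± 0.33), Orm2 (1.62 ± 0.22), Slc26a4 (1.59 ± 0.29), Il33 (1.59 ± 0.22) and the B cell chemokine Cxcl13 (1.49 ± 0.33). The lowest were Acaa1b (-1.16 ± 0.24), the oxidase Nox4 (-1.06 ± 0.26), Dpep1 (-1.04 ± 0.23), the neuropeptide Grp (-0.97 ± 0.20), Amy1 (-0.77 ± 0.13), Prelp (-0.77 ± 0.18), Ackr3 (-0.71 ± 0.15), Septin4 (-0.71 ± 0.17), Cyp2d22 (-0.69 ± 0.16) and Plpp3 (-0.69 ± 0.17). Cyp1b1 rose by 0.93 ± 0.22, Ccl2 by 0.90 ± 0.22 and S100a8 by 1.37 ± 0.28. Cyp1a1 (-0.65 ± 0.26, adjusted p = 0.212), Hmox1 (0.60 ± 0.16, adjusted p = 0.0581), Nqo1 (0.09 ± 0.14) and Clca1 (-0.80 ± 0.90) did not pass. Muc5ac (0.06 ± 0.18), Retnla (1.5 ± 0.44), Ccl11 (-0.14 ± 0.14), Il13 (-0.08 ± 0.10), Il5 (-0.16 ± 0.12), Epx (-0.08 ± 0.11) and Chil4 (-0.08 ± 0.27) did not either, while Hmox1 passed without saline replicate 2. Orm1, Orm2 and Il33 were the 3 of 20 leading genes that passed with any 1 array left out, and the other 17, Cyp1b1, Ccl2 and S100a8 lost their call without ADEP replicate 3. Orm2 was dim in saline and Amy1 in both groups. Nox4 fell to -0.69, Grp to -0.63 and Cyp2d22 to -0.39 without saline replicate 1.

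Every one of the 17 lists called after ADEP lost its call with an estimated correlation. For acute phase proteins, 11 rose and 0 fell of 15, 15 and 0 adjusted over the list alone (camera adjusted p = 1.66e-22, adjusted p = 0.0615 with an estimated correlation). Endothelial genes were lower, with Vwf at -0.55 ± 0.11, Cldn5 at -0.58 ± 0.12 and Ptprb at -0.69 ± 0.13: 0 rose and 4 fell of 19, 0 and 10 adjusted over the list alone (camera adjusted p = 2.08e-11, adjusted p = 0.127 with an estimated correlation). Unfolded protein response genes included Manf (0.82 ± 0.15) and Pdia6 (0.71 ± 0.15): 4 rose and 0 fell of 15, 8 and 0 adjusted over the list alone (camera adjusted p = 5.41e-07, adjusted p = 0.122 with an estimated correlation). Among metallothioneins and metal response genes, with Mt2 at 1.20 ± 0.31 and Hamp at 0.65 ± 0.15, 3 rose and 0 fell of 6, 5 and 0 adjusted over the list alone (camera adjusted p = 1.90e-05, adjusted p = 0.122 with an estimated correlation). Replication genes Mcm2 (0.83 ± 0.17) and Mcm5 (0.67 ± 0.15) rose in the cell cycle list: 3 rose and 0 fell of 24, 11 and 0 adjusted over the list alone (camera adjusted p = 1.43e-06, adjusted p = 0.158 with an estimated correlation). The ADEP count rested on single arrays, with 8 genes without ADEP replicate 3, 14 without saline replicate 1 and 34 without ADEP replicate 1. Vwf, Cldn5, Ptprb and the other genes of these lists given here lost their call without ADEP replicate 3, as did Vwf, Cldn5 and Ptprb without ADEP replicate 1. With heart and fat covariates 32 genes passed.

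After CDEP alone 283 genes were higher and 218 lower than in saline. Saa3 rose 7.56-fold, from 9.13 ± 0.78 to 12.05 ± 0.16 (adjusted p = 0.00151), and Orm1 by 2.87 ± 0.38 log2. They were followed by Lcn2 (2.37 ± 0.36), Cxcl1 (2.25 ± 0.33), Timp1 (2.23 ± 0.35), Cd177 (2.07 ± 0.41), Slc26a4 (2.06 ± 0.29), Cxcl5 (1.85 ± 0.33), Saa1 (1.74 ± 0.25) and the interleukin 1 receptor antagonist Il1rn (1.65 ± 0.26). The lowest genes were Acaa1b (-1.34 ± 0.24), Cyp2e1 (-1.04 ± 0.29), Grp (-1.01 ± 0.20), Nox4 (-0.99 ± 0.26), Abca8a (-0.92 ± 0.20), Itih5 (-0.86 ± 0.19), Scara5 (-0.86 ± 0.20), Scn3b (-0.81 ± 0.20), Rgs5 (-0.81 ± 0.14) and the matrix protein Ogn (-0.81 ± 0.23). Cyp1b1 rose by 0.97 ± 0.22, Hmox1 by 0.83 ± 0.16, Ccl2 by 1.25 ± 0.22 and S100a8 by 1.21 ± 0.28. Cyp1a1 (0.23 ± 0.26), Nqo1 (-0.21 ± 0.14), Muc5ac (0.23 ± 0.18), Clca1 (0.91 ± 0.90) and Retnla (1.26 ± 0.44) did not pass. The same held for Ccl11 (0.06 ± 0.14), Il13 (-0.18 ± 0.10), Il5 (-0.04 ± 0.12), Epx (-0.05 ± 0.11) and Chil4 (0.08 ± 0.27). Of the 20 leading genes 13 passed with any 1 array left out. Cyp2e1, Nox4, Abca8a, Itih5, Scara5, Scn3b and Ogn, and also Cyp1b1, Hmox1 and S100a8, lost their call without 1 or more of the 3 saline and 3 CDEP arrays. Saa1 was dim in saline. Without saline replicate 1 Nox4 stood at -0.62 and Scn3b at -0.43.

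For acute phase proteins after CDEP, 11 rose and 0 fell of 15, 13 and 0 adjusted over the list alone (camera adjusted p = 3.74e-20, adjusted p = 0.0543 with an estimated correlation). Unfolded protein response genes, which serve folding in the endoplasmic reticulum, included Manf (0.94 ± 0.15) and Hspa5 (0.61 ± 0.12): 6 rose and 0 fell of 15, 10 and 0 adjusted over the list alone (camera adjusted p = 1.36e-08, adjusted p = 0.0543 with an estimated correlation). Monocyte chemokines included Ccl12 at 1.19 ± 0.21 and Ccl9 at 1.10 ± 0.24: 4 rose and 0 fell of 8, 6 and 0 adjusted over the list alone (camera adjusted p = 1.93e-06, adjusted p = 0.0814 with an estimated correlation). In the alveolar type 1 list, with Rtkn2 at 0.50 ± 0.13, 2 rose and 0 fell of 8, 4 and 0 adjusted over the list alone (camera adjusted p = 0.00550, adjusted p = 0.189 with an estimated correlation). Smooth muscle and pericyte genes were lower: 0 rose and 1 fell of 12, 0 and 6 adjusted over the list alone (camera adjusted p = 0.000827, adjusted p = 0.189 with an estimated correlation). In the glucocorticoid-responsive list, where Lcn2 and Mt2 (1.34 ± 0.31) were the members that rose, 2 rose and 0 fell of 15, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0356, adjusted p = 0.542 with an estimated correlation). Immediate early genes gave 0 rose and 0 fell of 16, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.199 with an estimated correlation). All 27 called lists lost their call with an estimated correlation. The glucocorticoid list lost its call without saline replicates 1 or 3 or CDEP replicates 2 or 3, and the immediate early list without saline replicates 2 or 3 or CDEP replicates 1 or 2. Ccl9 lost it without CDEP replicate 2, Rtkn2 without saline replicate 1 or CDEP replicates 1 or 2, and Mt2 without saline replicate 1 or CDEP replicates 2 or 3. The alveolar type 1 median went from 0.38 to 0.14 without saline replicate 1. The heart muscle list was lower, median -0.52, and -0.29 without saline replicate 3: 0 rose and 2 fell of 20, 0 and 15 adjusted over the list alone (camera adjusted p = 9.51e-08, adjusted p = 0.208 with an estimated correlation). Of the RNA quality measures, the Gapdh signal of 3' over 5' probes was 0.0607 ± 0.0617 log2 in CDEP and 0.362 ± 0.285 in saline (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). That of Actb was 0.658 ± 0.0271 and 1.01 ± 0.196 (exact two-sided permutation p = 0.1). With both differences as covariates only Orm1, Csf2 and Cd177 passed. The median size of the 501 changes went from 0.50 to 0.39 log2 while the median SE went from 0.12 to 0.15, and all 501 kept their sign. Both measures separated the CDEP arrays from the saline arrays without overlap. This fit therefore cannot cleanly separate an effect of RNA quality from one of CDEP. Leaving out 1 array gave 147 genes without saline replicate 1, 283 without saline replicate 3, and 188, 144 and 187 without CDEP replicates 1, 2 and 3.

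The calls of the particles overlapped, and they share the 3 saline arrays. Of genes higher in at least 1 particle group 91 were higher in all 3, and 12 genes were lower in all 3. NDEP and CDEP shared 153 higher genes, NDEP and ADEP 103, and ADEP and CDEP 106. Independent lists would share 6.37, 3.24 and 3.29, but these numbers leave out the shared arrays. Across genes, which are not independent replicates, the correlation of fold changes was 0.824 for NDEP and CDEP, and 0.497 in simulated unchanged groups sharing the saline arrays. The covariance was 0.0417, and 0.00816 there, though real shared arrays may add more. With saline arrays divided so that none served both particles, in all 6 ways, the correlation was 0.339 to 0.558 for NDEP and CDEP, 0.302 to 0.548 for NDEP and ADEP and 0.251 to 0.541 for ADEP and CDEP. In those fits NDEP and CDEP shared 5 to 61 higher genes, with 1 or 2 saline arrays for each. Fewer arrays also lower such counts, so the part of shared calls due to shared arrays is not known. The covariance with no shared saline array had a median of 0.0313 for NDEP and CDEP, against 0.0417 with all shared. For NDEP and ADEP it was 0.0264 against 0.0374, and for ADEP and CDEP 0.0254 against 0.0370. Most of the covariance thus remained without shared arrays.

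OVA alone gave no gene past the threshold against saline in the limma test, while 818 of 12393 genes had an unadjusted p under 0.05. The 3 genes with the smallest p, none past the threshold, were Timm10b (0.59 ± 0.10, adjusted p = 0.0798), the phosphate transporter Slc34a2 (0.59 ± 0.12) and Rps4l (0.73 ± 0.16). Clca1, a goblet cell protein of mucus (Entrez gene 23844), stood at 2.09 ± 0.90, and its 3 OVA mice lay at 6.79, 3.80 and 9.29 against 4.54 ± 0.97 in saline, with OVA replicate 2 below the 25th percentile of its array. Muc5ac (0.11 ± 0.18), Chil4 (0.08 ± 0.27), Ccl11 (-0.26 ± 0.14), Retnla (-0.31 ± 0.44), Il13 (-0.10 ± 0.10), Il5 (-0.08 ± 0.12) and Epx (-0.14 ± 0.11) did not pass. Neither did Saa3 (-0.20 ± 0.49), Cxcl1 (-0.32 ± 0.33), Ccl2 (0.06 ± 0.22), S100a8 (0.62 ± 0.28), Cyp1a1 (0.01 ± 0.26), Cyp1b1 (0.09 ± 0.22), Hmox1 (0.00 ± 0.16) and Nqo1 (-0.19 ± 0.14). Alveolar type 2 genes were called as a list, median 0.33: 0 rose and 0 fell of 13, 4 and 0 adjusted over the list alone (camera adjusted p = 2.11e-09, adjusted p = 0.310 with an estimated correlation). That median was 0.14 without saline replicate 1, the array with the highest Gapdh signal of 3' over 5' probes (0.679 log2). For mesothelial genes, with no call without saline replicate 1, 0 rose and 0 fell of 7, 2 and 0 adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.310 with an estimated correlation). Extracellular matrix and fibroblast genes were lower, median -0.16: 0 rose and 0 fell of 17, 0 and 4 adjusted over the list alone (camera adjusted p = 0.00473, adjusted p = 0.829 with an estimated correlation). They lost the call without saline replicate 1 (-0.07) or OVA replicate 3 (-0.10) and stood at -0.27 without saline replicate 3. All 7 called lists lost their call with an estimated correlation. With array weights 12 genes passed, and without saline replicate 1 there was 1, Timm10b.

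NDEP given with OVA was followed by a rise of allergic airway and mucus genes over OVA alone. 216 genes were higher and 41 lower. Clca1 rose 31.1-fold, to 11.59 ± 0.20 (4.96 ± 0.90 log2, adjusted p = 0.00237), and Slc26a4 15.7-fold (adjusted p = 1.08e-08). The Clca1 value was 11.7-fold without OVA replicate 2 and 78.4-fold without OVA replicate 3. The chitinase-like proteins Chil4 (Entrez gene 104183) and Chil3 rose by 2.66 ± 0.27 and 2.32 ± 0.33, Retnla by 2.30 ± 0.44 and the goblet cell disulfide isomerase Agr2 by 2.16 ± 0.45. Cd177 (3.55 ± 0.41), Orm1 (2.90 ± 0.38), Cxcl5 (2.53 ± 0.33) and Saa3 (2.12 ± 0.49) complete the 10 highest. The lowest genes were the heme synthesis enzyme Alas2 (-1.74 ± 0.46), Hnrnpab (-1.09 ± 0.23), Pon1 (-1.0 ± 0.21), Fabp3 (-0.99 ± 0.16), Ehd2 (-0.96 ± 0.16), the atrial light chains Myl7 (-0.90 ± 0.23) and Myl4 (-0.79 ± 0.20), Scara5 (-0.84 ± 0.20), Gsta3 (-0.81 ± 0.11) and Klhl24 (-0.80 ± 0.19). The gel-forming mucin Muc5ac rose by 1.37 ± 0.18, the eosinophil chemokine Ccl11 by 0.95 ± 0.14, Cxcl1 by 1.89 ± 0.33 and Hmox1 by 0.72 ± 0.16. Cyp1b1 (0.76 ± 0.22, adjusted p = 0.0721), Ccl2 (0.80 ± 0.22, adjusted p = 0.0523), S100a8 (0.08 ± 0.28), Cyp1a1 (0.08 ± 0.26) and Nqo1 (-0.24 ± 0.14) did not pass. Nor did Il13 (0.18 ± 0.10), Il5 (0.00 ± 0.12) and the eosinophil peroxidase Epx (0.00 ± 0.11), while Cyp1b1 passed without NDEP_OVA replicate 2. Chil4, Orm1 and Ccl11 were dim in OVA. Of the 20 leading genes 11 passed with any 1 array left out. Agr2, Saa3, Alas2, Hnrnpab, Pon1, Myl7, Myl4, Scara5 and Klhl24, and also Hmox1, lost their call without 1 or more of the 3 OVA and 3 NDEP_OVA arrays. Retnla stood at 1.33 and Saa3 at 1.19 without OVA replicate 2.

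In the Th2 and allergic airway list after NDEP with OVA, 13 rose and 0 fell of 26, 13 and 0 adjusted over the list alone (camera adjusted p = 1.45e-18, adjusted p = 0.000280 with an estimated correlation), with the eosinophil-associated ribonuclease Rnase2a, dim in OVA, at 1.91 ± 0.26. Of the mucus and goblet cell genes, with Fcgbp at 1.62 ± 0.25 and Scin at 1.11 ± 0.17, 9 rose and 0 fell of 12, 11 and 0 adjusted over the list alone (camera adjusted p = 8.94e-19, adjusted p = 0.0229 with an estimated correlation). Alveolar macrophage and phagocyte genes included the proteases Ctsk (1.68 ± 0.22) and Mmp12 (1.97 ± 0.28): 9 rose and 0 fell of 19, 13 and 0 adjusted over the list alone (camera adjusted p = 1.75e-15, adjusted p = 0.0229 with an estimated correlation). Coagulation, protease and remodelling genes included F10 (1.12 ± 0.14) and F7 (0.87 ± 0.13): 5 rose and 0 fell of 16, 8 and 0 adjusted over the list alone (camera adjusted p = 1.35e-06, adjusted p = 0.0229 with an estimated correlation). Dendritic cell markers, with Ccl22 at 0.77 ± 0.13 and Batf3 at 0.58 ± 0.11, gave 4 rose and 0 fell of 14, 5 and 0 adjusted over the list alone (camera adjusted p = 2.44e-08, adjusted p = 0.0229 with an estimated correlation). Club cell genes were lower, with Cyp2f2 at -0.48 ± 0.11: 0 rose and 2 fell of 12, 0 and 6 adjusted over the list alone (camera adjusted p = 4.38e-07, adjusted p = 0.0229 with an estimated correlation). 12 of 26 called lists kept their call with an estimated correlation. Cholesterol synthesis genes, led by Mvd (0.65 ± 0.11), lost it: 1 rose and 0 fell of 13, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0486, adjusted p = 0.464 with an estimated correlation). Erythrocyte genes lost it too: 0 rose and 1 fell of 8, 0 and 3 adjusted over the list alone (camera adjusted p = 0.0161, adjusted p = 0.127 with an estimated correlation). The cholesterol list had no call without OVA replicates 2 or 3 or NDEP_OVA replicate 1, nor the erythrocyte list without OVA replicate 3. Batf3 lost its call without NDEP_OVA replicate 3, and Cyp2f2 without that array or OVA replicates 2 or 3. Heart muscle genes were lower, median -0.51: 0 rose and 3 fell of 20, 0 and 13 adjusted over the list alone (camera adjusted p = 1.07e-14, adjusted p = 0.0598 with an estimated correlation). The Actb signal of 3' over 5' probes was 1.01 ± 0.0696 log2 in this group and 0.816 ± 0.0930 in OVA (exact two-sided permutation p = 0.1, the smallest possible). Leaving out an array gave 78 genes without NDEP_OVA replicate 3, 79 without OVA replicate 2, 159 without OVA replicate 3 and 423 without NDEP_OVA replicate 2.

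After ADEP given with OVA 78 genes were higher and 7 lower than with OVA alone. Slc26a4 rose 6.83-fold (adjusted p = 1.70e-05) and Timp1 6.03-fold (adjusted p = 0.000412). They were followed by Saa3 (2.41 ± 0.49), Cxcl5 (2.32 ± 0.33), Cd177 (2.13 ± 0.41), Retnla (2.12 ± 0.44), Lcn2 (1.98 ± 0.36), Cxcl1 (1.93 ± 0.33), Orm1 (1.93 ± 0.38) and arginase Arg1 (1.92 ± 0.33). The 7 lower genes were Aox3 (-0.75 ± 0.16), Akr1c14 (-0.69 ± 0.15), catalase Cat (-0.68 ± 0.13), Abcc9 (-0.66 ± 0.15), Gsta3 (-0.60 ± 0.11), Bambi (-0.58 ± 0.10) and Prkcq (-0.49 ± 0.09). Ccl11 (Entrez gene 20292) rose by 1.17 ± 0.14 and Ccl2 by 1.26 ± 0.22. Clca1 stood above OVA without passing (2.99 ± 0.90, adjusted p = 0.151), as did Chil4 (0.72 ± 0.27, adjusted p = 0.252) and Muc5ac (0.50 ± 0.18, adjusted p = 0.234). Cyp1a1 (-0.53 ± 0.26), Cyp1b1 (0.71 ± 0.22), Hmox1 (0.57 ± 0.16), Nqo1 (-0.20 ± 0.14), S100a8 (0.51 ± 0.28), Il13 (0.08 ± 0.10), Il5 (0.18 ± 0.12) and Epx (0.29 ± 0.11) did not pass either. Without OVA replicate 3 Clca1 passed, at 4.32, and without OVA replicate 2 it stood at 1.58, Saa3 at 1.48 and Retnla at 1.15. Orm1, Arg1 and Ccl11 were dim in OVA and Abcc9 in ADEP_OVA. Slc26a4, Timp1, Cxcl5, Arg1, Gsta3 and Bambi were the 6 of 17 leading genes that passed with any 1 array left out. The other 11 lost their call without 1 or more of the 3 OVA and 3 ADEP_OVA arrays.

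Monocyte chemokines were called after ADEP with OVA, with Ccl12, dim in OVA, at 1.35 ± 0.21, Ccl7 at 1.29 ± 0.22 and Ccl8 at 1.46 ± 0.25: 5 rose and 0 fell of 8, 7 and 0 adjusted over the list alone (camera adjusted p = 1.47e-12, adjusted p = 0.0187 with an estimated correlation). For Th2 and allergic airway genes, with Ccl17 at 1.20 ± 0.18, 6 rose and 0 fell of 26, 14 and 0 adjusted over the list alone (camera adjusted p = 3.25e-14, adjusted p = 0.00118 with an estimated correlation). In the monocyte marker list, with Ms4a6d at 1.31 ± 0.19, 3 rose and 0 fell of 10, 5 and 0 adjusted over the list alone (camera adjusted p = 8.34e-06, adjusted p = 0.0452 with an estimated correlation). Coagulation, protease and remodelling genes, with Tnc at 0.89 ± 0.16, gave 6 rose and 0 fell of 16, 8 and 0 adjusted over the list alone (camera adjusted p = 1.24e-08, adjusted p = 0.0187 with an estimated correlation). The club cell list was lower: 0 rose and 1 fell of 12, 0 and 4 adjusted over the list alone (camera adjusted p = 4.45e-07, adjusted p = 0.0436 with an estimated correlation). These 5 of 23 called lists kept their call with an estimated correlation, whereas the mucus list lost it: 0 rose and 0 fell of 12, 10 and 0 adjusted over the list alone (camera adjusted p = 5.20e-08, adjusted p = 0.108 with an estimated correlation). The mucus median went from 0.63 to 0.42 without OVA replicate 2. NK and cytotoxic markers were lower, median -0.26, with no call without ADEP_OVA replicate 2: 0 rose and 0 fell of 10, 0 and 1 adjusted over the list alone (camera adjusted p = 0.00764, adjusted p = 0.361 with an estimated correlation). Without OVA replicate 2 Tnc lost its call and 18 genes passed, without OVA replicate 3 52 and without ADEP_OVA replicate 2 54. The count rose to 130 with RNA quality and 195 with heart and fat covariates.

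After CDEP given with OVA 449 genes were higher and 145 lower than with OVA alone, with allergic, mucus and interferon response genes at the top. Clca1 rose 39.6-fold, to 11.93 ± 0.41 (adjusted p = 0.000670) and Slc26a4 17.6-fold (adjusted p = 4.52e-09). The Clca1 value was 14.8-fold without OVA replicate 2 and 99.6-fold without OVA replicate 3. Chil4 rose to 8.10 ± 0.92 (adjusted p = 4.91e-09) from 4.48 ± 0.13, which lies below the 25th percentile of each OVA array (4.52 to 4.58), and Arg1, Orm1 and Ccl11 were likewise dim in OVA. Cd177 (3.48 ± 0.41), Arg1 (3.33 ± 0.33), Agr2 (2.97 ± 0.45), Cxcl5 (2.75 ± 0.33) and Orm1 (2.56 ± 0.38) were in the same top 10. So were Cxcl9, an interferon-gamma-induced T cell chemokine (Entrez gene 17329, 2.86 ± 0.33), and the interferon-inducible GTPase Iigp1 (2.54 ± 0.30). The 10 lowest were Hnrnpab (-1.41 ± 0.23), Scara5 (-1.26 ± 0.20), Ehd2 (-1.16 ± 0.16), Fzd4 (-1.15 ± 0.21), Fabp3 (-1.14 ± 0.16) and 5 genes of striated muscle, myoglobin Mb (-1.18 ± 0.22), Myl7 (-1.18 ± 0.23), Myh6 (-1.16 ± 0.24), Tcap (-1.15 ± 0.22) and Tnni3 (-1.12 ± 0.19). Muc5ac rose by 1.93 ± 0.18, Ccl11 by 1.39 ± 0.14, Retnla by 2.48 ± 0.44, Cxcl1 by 2.32 ± 0.33, Ccl2 by 1.38 ± 0.22 and Saa3 by 2.19 ± 0.49. Cyp1a1 (0.44 ± 0.26), Cyp1b1 (0.45 ± 0.22), Hmox1 (0.50 ± 0.16), Nqo1 (-0.18 ± 0.14), S100a8 (0.33 ± 0.28), Il13 (-0.06 ± 0.10), Il5 (-0.02 ± 0.12) and Epx (-0.07 ± 0.11) did not pass. All 20 leading genes passed with any 1 array left out. Saa3 did not without OVA replicate 2 (1.26) or CDEP_OVA replicate 2, Retnla stood at 1.51 without OVA replicate 2, and Hmox1 passed without CDEP_OVA replicate 3.

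In the interferon response list after CDEP with OVA, 15 rose and 0 fell of 20, 19 and 0 adjusted over the list alone (camera adjusted p = 1.40e-25, adjusted p = 0.0129 with an estimated correlation), with Igtp at 1.83 ± 0.22 and Cxcl10 at 2.18 ± 0.29. Of mucus and goblet cell genes, 11 rose and 0 fell of 12, 11 and 1 adjusted over the list alone (camera adjusted p = 1.37e-19, adjusted p = 0.0129 with an estimated correlation). The Th2 and allergic airway list gave 14 rose and 0 fell of 26, 14 and 0 adjusted over the list alone (camera adjusted p = 3.92e-15, adjusted p = 0.00104 with an estimated correlation). Unfolded protein response genes included Sdf2l1 (1.11 ± 0.18) and Creld2 (1.19 ± 0.20): 9 rose and 0 fell of 15, 12 and 0 adjusted over the list alone (camera adjusted p = 5.46e-13, adjusted p = 0.00990 with an estimated correlation). Among monocyte chemokines, with Ccl8 at 2.05 ± 0.25, 6 rose and 0 fell of 8, 6 and 0 adjusted over the list alone (camera adjusted p = 3.21e-11, adjusted p = 0.0149 with an estimated correlation). These lists kept their call with an estimated correlation, 8 of 24 in all. Heat shock genes, with Hsph1 at 1.03 ± 0.27 and Bag3 at 0.56 ± 0.11, lost it: 5 rose and 0 fell of 12, 11 and 0 adjusted over the list alone (camera adjusted p = 3.85e-09, adjusted p = 0.0776 with an estimated correlation). Among NK and cytotoxic markers Gzmb rose by 0.82 ± 0.17: 1 rose and 0 fell of 10, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0330, adjusted p = 0.455 with an estimated correlation). Heart muscle genes were lower, median -0.80, with Actc1 at -0.92 ± 0.15: 0 rose and 13 fell of 20, 0 and 16 adjusted over the list alone (camera adjusted p = 1.22e-15, adjusted p = 0.0695 with an estimated correlation). Fat genes were lower too, median -0.40: 0 rose and 1 fell of 10, 0 and 3 adjusted over the list alone (camera adjusted p = 0.00130, adjusted p = 0.152 with an estimated correlation). The matrix proteins Dcn (-0.87 ± 0.20) and Lum (-0.82 ± 0.21) fell in the extracellular matrix list: 0 rose and 3 fell of 17, 0 and 4 adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.508 with an estimated correlation). The matrix list had no call without OVA replicates 1 or 2 or CDEP_OVA replicate 1, and the NK list none without OVA replicate 3 or CDEP_OVA replicates 1 or 2. Gzmb lost its call without CDEP_OVA replicate 2, and Hsph1, Dcn and Lum without that array among others. 217 genes passed without CDEP_OVA replicate 2, 223 without OVA replicate 2, 384 without OVA replicate 3 and 385 with heart and fat covariates.

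**Figure D2:**
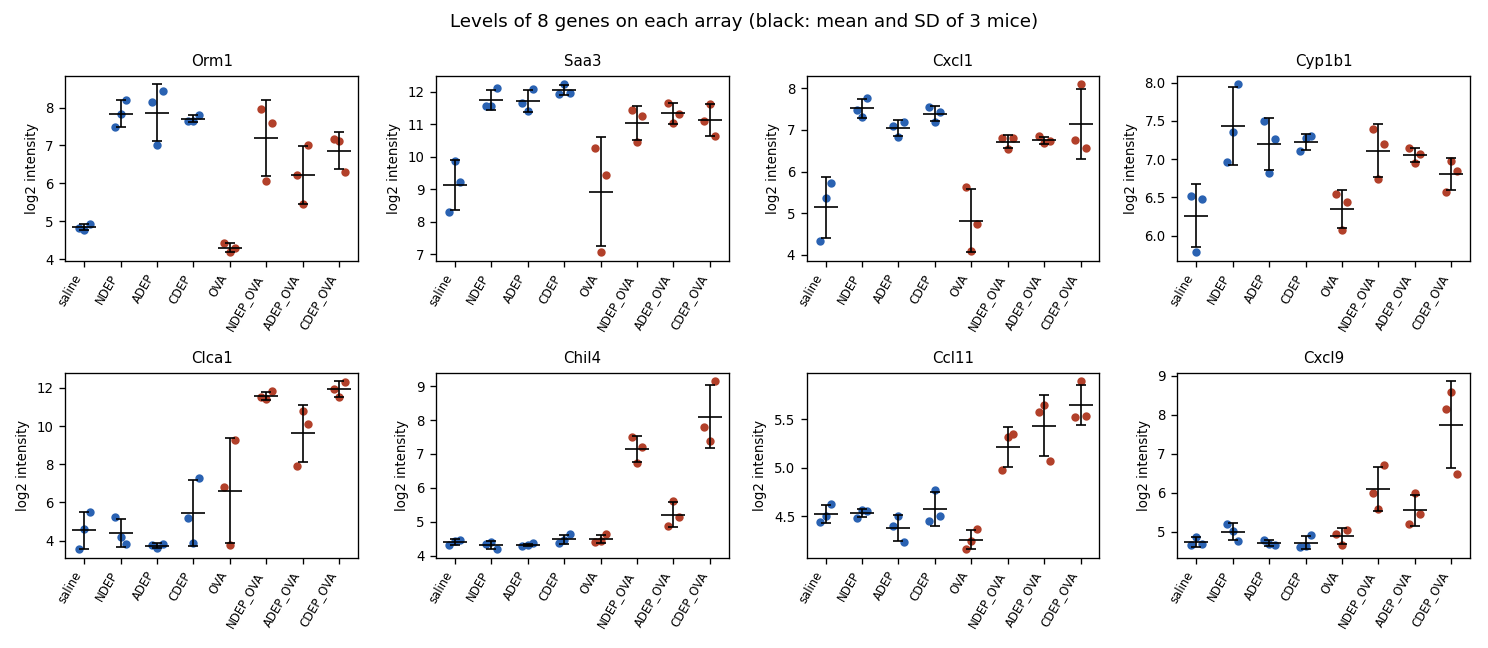
Log2 intensity of 8 genes on each of the 24 arrays, by group, with blue points for groups without OVA and red points for groups with OVA. Black marks are the mean and SD of 3 mice, and Clca1 in OVA alone spans 3.80 to 9.29 while CDEP_OVA lies at 11.93 ± 0.41.

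The particle comparisons with OVA also shared calls, and they share the 3 OVA arrays. 54 genes were higher and 2 lower for all 3 particles. NDEP_OVA and CDEP_OVA shared 174 higher genes, with a correlation of fold changes of 0.820 across genes and 0.50 in simulated unchanged groups. With no OVA array used for both particles it was 0.514 to 0.672, and 0.293 to 0.563 for NDEP_OVA and ADEP_OVA and 0.203 to 0.543 for ADEP_OVA and CDEP_OVA. Part of the overlap may come from the shared arrays. The covariance with no shared OVA array had a median of 0.0396 for NDEP_OVA and CDEP_OVA, against 0.0473 with all shared. For NDEP_OVA and ADEP_OVA it was 0.0211 against 0.0285, and for ADEP_OVA and CDEP_OVA 0.0223 against 0.0295. Comparisons without and with OVA share no array, and there the same particle gave correlations across genes of 0.523 for NDEP, 0.302 for ADEP and 0.424 for CDEP. Pairs of different particles gave 0.399 to 0.493, and for ADEP and CDEP a different particle with OVA gave a higher value than the same one. The ADEP value was 0.189 without OVA replicate 2 and 0.198 without ADEP_OVA replicate 3 or saline replicate 1. 21 genes were higher in all 6 particle comparisons and none lower. They were the chemokines Ccl3, Ccl9, Ccl12, Cxcl1 and Cxcl13, the acute phase genes Lcn2, Orm1, Saa3 and Serpina3n, and Cd177, Chil1, Clec4d, Il1rn, Ms4a6d, Ncf4, Noxo1, Slc26a4, Slc39a4, Slc6a20a, Steap4 and Timp1, a set counted after the values were seen. Across the 6, Orm1, dim in OVA, ranged from 1.93 to 3.03 and Timp1 from 1.88 to 2.59.

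Averaged over saline and the 3 particle backgrounds, mice given OVA had 113 genes higher and 193 lower than mice without it. OVA alone against saline passed no gene, so this average does not show an effect of OVA without particles. Clca1 was higher (5.40 ± 0.45 log2, n = 12 mice per side, adjusted p = 6.58e-08). It was dim in NDEP and ADEP and stood at 4.54 ± 0.97 in saline and 5.45 ± 1.72 in CDEP. Other goblet cell and allergic airway genes were Agr2 (1.88 ± 0.23), Chil4 (1.86 ± 0.13), Arg1 (1.81 ± 0.17), Rnase2a (1.49 ± 0.13), the chitinase Chia1 (1.39 ± 0.12), Slc26a4 (1.28 ± 0.15) and Fcgbp (1.25 ± 0.12). Cxcl9 (1.28 ± 0.16) and the guanylate-binding protein Gbp6 (1.0 ± 0.10) complete the 10 highest. Among the 10 lowest were Orm1 (-0.91 ± 0.19), Hnrnpab (-0.87 ± 0.12) and 8 muscle genes, Myl7 (-0.70 ± 0.12), Csrp3 (-0.69 ± 0.12), Smpx (-0.68 ± 0.12), Tcap (-0.67 ± 0.11), Ckmt2 (-0.64 ± 0.14), Myoz2 (-0.64 ± 0.11), Sln (-0.61 ± 0.13) and Cox6a2 (-0.61 ± 0.09). Chil4, Arg1 and Rnase2a were dim in OVA alone and in all groups without OVA, Ccl11 in those but CDEP, and Orm1 in OVA alone. Muc5ac rose by 0.92 ± 0.09 and Ccl11 by 0.64 ± 0.07, and Nqo1 stood lower at -0.30 ± 0.07 (adjusted p = 0.0144). Cyp1a1 (0.07 ± 0.13), Cyp1b1 (-0.20 ± 0.11), Hmox1 (-0.12 ± 0.08), Cxcl1 (-0.42 ± 0.17), Ccl2 (0.14 ± 0.11), Saa3 (-0.55 ± 0.24) and S100a8 (-0.15 ± 0.14) did not pass. Retnla (0.46 ± 0.22), Il13 (0.04 ± 0.05), Il5 (0.04 ± 0.06) and Epx (-0.07 ± 0.06) did not pass either, except for Retnla without OVA replicate 2.

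For Th2 and allergic airway genes on average over backgrounds, 11 rose and 0 fell of 26, 12 and 1 adjusted over the list alone (camera adjusted p = 7.99e-18, adjusted p = 0.000396 with an estimated correlation). For mucus and goblet cell genes, 8 rose and 0 fell of 12, 10 and 0 adjusted over the list alone (camera adjusted p = 5.78e-20, adjusted p = 0.0223 with an estimated correlation). Both kept their call with an estimated correlation, unlike the other 14 called lists. In OVA alone against saline the list mean changed by 0.0025 ± 0.070 log2 for Th2 genes, against 0.513 ± 0.035 averaged. For mucus genes it was 0.219 ± 0.279 against 1.04 ± 0.14, and for interferon genes 0.083 ± 0.159 against 0.403 ± 0.080. These averages thus came mainly from mice given particles with OVA. Interferon response genes, with Igtp at 0.87 ± 0.11 and Gbp2 at 0.51 ± 0.09, gave 8 rose and 0 fell of 20, 16 and 0 adjusted over the list alone (camera adjusted p = 5.97e-19, adjusted p = 0.0527 with an estimated correlation). Acute phase proteins were lower, with Orm2, dim in saline, OVA and ADEP_OVA, at -0.59 ± 0.11: 0 rose and 4 fell of 15, 0 and 8 adjusted over the list alone (camera adjusted p = 5.63e-08, adjusted p = 0.235 with an estimated correlation). Extracellular matrix genes fell, with Col1a1 at -0.45 ± 0.07, and had no call without saline replicate 1, ADEP_OVA replicate 3 or CDEP_OVA replicate 1: 0 rose and 4 fell of 17, 0 and 6 adjusted over the list alone (camera adjusted p = 0.00837, adjusted p = 0.509 with an estimated correlation). Heart muscle genes were lower, median -0.42: 0 rose and 12 fell of 20, 0 and 16 adjusted over the list alone (camera adjusted p = 5.97e-19, adjusted p = 0.0871 with an estimated correlation). 218 of the 306 genes had the same sign in all 4 backgrounds, and the 20 leading genes passed in each of the 24 leave-one-out fits. With heart and fat scores as covariates 44 genes passed.

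**Figure D3:**
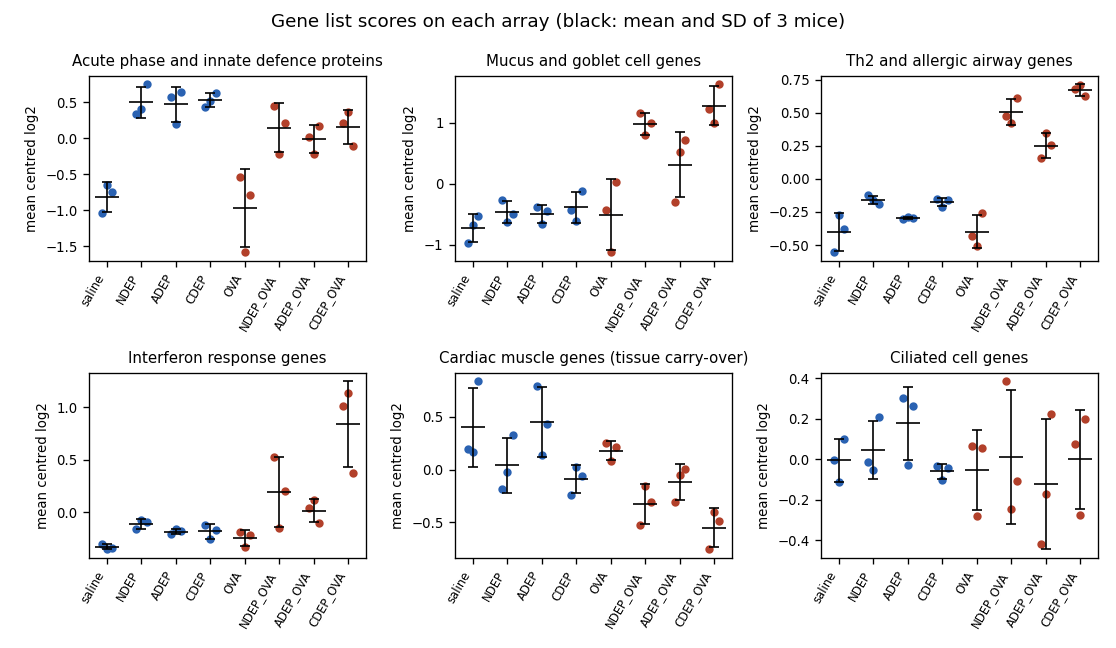
Mean centred log2 value of 6 gene lists on each of the 24 arrays, by group, blue without OVA and red with OVA, with mean and SD of 3 mice in black. The Th2 and allergic airway list lies above 0 in every mouse given particles with OVA and below 0 in every other mouse.

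Few genes passed the threshold for a different response to a particle between mice with and without OVA, tested as an interaction. For NDEP these were 3 genes, all with a larger change under OVA: Chil4 (2.75 ± 0.38, adjusted p = 0.00177), Rnase2a (2.06 ± 0.37, adjusted p = 0.0386) and the lectin Cd209e (1.02 ± 0.16, adjusted p = 0.00855). For ADEP they were Ccl11 (1.32 ± 0.19, adjusted p = 0.00543), Timm10b (-0.80 ± 0.15, adjusted p = 0.0496) and Bambi (-0.78 ± 0.14, adjusted p = 0.0480). For CDEP there were 46, 32 with a more positive and 14 with a more negative change under OVA. The 5 highest were Chil4 (3.54 ± 0.38, adjusted p = 1.83e-05), Arg1 (3.1 ± 0.47), Cxcl9 (2.87 ± 0.46), Iigp1 (2.45 ± 0.43) and Chil3 (2.40 ± 0.47), and the 5 lowest Ehd2 (-1.32 ± 0.23), Rps4l (-1.07 ± 0.23), the iron hormone Hamp (-1.02 ± 0.21), Rraga (-0.91 ± 0.15) and Tmem243 (-0.86 ± 0.18). Chil4, Rnase2a, Cd209e, Arg1 and Ccl11 were dim in all groups of these tests but the one given particles with OVA. The Th2 and allergic airway list was called for all 3 particles and kept with an estimated correlation, with adjusted p = 0.00630 for NDEP, 0.0203 for ADEP and 0.0158 for CDEP. Of its 26 measured members 2 had a call for a more positive change under OVA for NDEP, 1 for ADEP and 8 for CDEP, and 9, 7 and 9 adjusted over the list alone. Alveolar type 2 genes went the other way in all 3, with medians of -0.37, -0.49 and -0.44, or -0.16, -0.31 and -0.27 without saline replicate 1, which all 3 share. They lost their calls with an estimated correlation (adjusted p = 0.440, 0.319 and 0.432). The CDEP count was 17 without OVA replicate 2, 26 without OVA replicate 3, 22 without CDEP replicate 2, 30 without saline replicate 1, 73 without saline replicate 2 and 13 with RNA quality covariates. ADEP gave 19 genes without ADEP_OVA replicate 3, 2 without saline replicate 1, 1 in every other leave-one-out fit and 0 with heart and fat scores as covariates. NDEP gave 5 without OVA replicate 3 and 6 without NDEP_OVA replicate 1. It gave 1 with RNA quality covariates. Rnase2a lost its call in 10 of 12 leave-one-out fits, Timm10b in 10 and Bambi in 11. For CDEP 6 of the 10 leading genes passed in each, and Chil3, Rps4l, Hamp and Tmem243 lost their call without 1 or more arrays.

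Compared directly without OVA, the 3 particles had few or no genes past the threshold. Vnn1, an enzyme of pantothenate recycling, was the only gene past the threshold between ADEP and NDEP, lower with ADEP (-1.14 ± 0.18, adjusted p = 0.0199). It passed in no leave-one-out fit without NDEP replicates 2 or 3 or ADEP replicates 1 or 2, where 0 genes passed. It also failed with RNA quality covariates and with only these 2 groups fitted. CDEP and NDEP gave 0 genes in limma, and 1 with only these 2 groups fitted (734 at an unadjusted p under 0.05). The nearest were Slc40a1 (-0.64 ± 0.12, 95% interval -0.90 to -0.39, adjusted p = 0.252), 2410004B18Rik (-0.39 ± 0.08) and Ikbip (-0.47 ± 0.11), none past it. CDEP and ADEP also gave 0 (828 at an unadjusted p under 0.05), with Actc1 (-0.66 ± 0.15, 95% interval -0.97 to -0.34, adjusted p = 0.423), B3gnt5 (-0.53 ± 0.12) and Rpap2 (-0.36 ± 0.08) nearest. The heart muscle list was lower with CDEP than ADEP, median -0.59: 0 rose and 0 fell of 20, 0 and 17 adjusted over the list alone (camera adjusted p = 1.42e-17, adjusted p = 0.344 with an estimated correlation). Complement components were lower with ADEP than NDEP, median -0.55: 0 rose and 0 fell of 7, 0 and 3 adjusted over the list alone (camera adjusted p = 7.65e-08, adjusted p = 0.0573 with an estimated correlation). A count of 0 does not show that the particles act alike.

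With OVA, CDEP and ADEP differed at 177 genes, 101 higher and 76 lower with CDEP. Chil4 was 7.45-fold higher (2.90 ± 0.27 log2, adjusted p = 1.03e-06), followed by Cxcl9 (2.19 ± 0.33), Agr2 (1.75 ± 0.45, or 1.11 without ADEP_OVA replicate 1), Iigp1 (1.64 ± 0.30) and Gbp6 (1.59 ± 0.21). The lowest were Ehd2 (-1.01 ± 0.16), Mb (-0.99 ± 0.22), Cox6a2 (-0.91 ± 0.18), Fabp3 (-0.89 ± 0.16) and Fbln1 (-0.80 ± 0.13). Of these 10 genes 6 passed with any 1 array left out, and Agr2, Iigp1, Mb and Cox6a2 lost their call without 1 or more arrays. Interferon response genes were higher, median 0.74: 9 rose and 0 fell of 20, 17 and 0 adjusted over the list alone (camera adjusted p = 3.72e-19, adjusted p = 0.138 with an estimated correlation). For mucus and goblet cell genes, 5 rose and 0 fell of 12, 9 and 1 adjusted over the list alone (camera adjusted p = 1.16e-09, adjusted p = 0.164 with an estimated correlation). Heart muscle genes were lower, median -0.49: 0 rose and 2 fell of 20, 0 and 11 adjusted over the list alone (camera adjusted p = 4.89e-06, adjusted p = 0.463 with an estimated correlation). Clca1, called over OVA alone for CDEP and not for ADEP, did not differ between both past the threshold (2.32 ± 0.90, adjusted p = 0.149). ADEP_OVA and NDEP_OVA differed at Chil4 (-1.94 ± 0.27, adjusted p = 0.00190) and Fabp5 (-0.96 ± 0.16, adjusted p = 0.0222), both lower with ADEP, and Fabp5 lost its call without NDEP_OVA replicates 2 or 3 or ADEP_OVA replicates 1 or 3. That count was 6 without NDEP_OVA replicate 1, 4 and 5 without ADEP_OVA replicates 2 and 3, and 1 without NDEP_OVA replicates 2 or 3 or ADEP_OVA replicate 1. CDEP_OVA and NDEP_OVA differed at Gbp6, higher with CDEP by 1.54 ± 0.21 (adjusted p = 0.00160). There 30 genes passed without CDEP_OVA replicate 3 and 13 without NDEP_OVA replicate 1. With only these 2 groups fitted 0 passed. The 177 genes became 35 without ADEP_OVA replicate 1 or CDEP_OVA replicate 2, 60 without ADEP_OVA replicate 3, 86 without CDEP_OVA replicate 3, 330 without ADEP_OVA replicate 2 and 386 without CDEP_OVA replicate 1. With CDEP_OVA and ADEP_OVA fitted alone 19 genes passed, and 56 with heart and fat covariates.

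Several lists stayed uncalled by camera in the comparisons with saline or OVA alone and in the averaged OVA effect. For the 17 T cell markers the median with CDEP and OVA was 0.01 (camera adjusted p = 0.838). Eosinophil markers had a median of -0.13 there (camera adjusted p = 0.164) and mast cell and basophil markers -0.03 (camera adjusted p = 0.580). B cell and plasma cell markers stood at 0.11, with the IgE receptor Fcer2a at 0.71 ± 0.17 as the 1 of 14 members that rose, though not without OVA replicates 2 or 3 or CDEP_OVA replicates 1 or 2. Thymus and lymph node genes stood at -0.10, with Cxcl13 at 1.71 ± 0.33 and Fcer2a as the 2 of 11 that rose. Ciliated cell genes stood at 0.01 (camera adjusted p = 0.809) and skeletal muscle genes at -0.15 (camera adjusted p = 0.0785).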

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

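The tests chosen only after the results were seen are those of dilution, T cells, NK cells, every explanation for the Clca1 spread, all counts over other splits of the arrays, the fits with RNA quality or heart and fat covariates, and the run of the heart and fat correlation on all list members. The sizes for Chil4, Rnase2a, Cd209e, Arg1 and Ccl11 are uncertain, since they lay below the 25th percentile of the arrays in all groups compared but the one given both. Interaction results were picked out because a particle effect differed between mice with and without OVA by the test of that difference, and groups of 3 are too small for a test of single far arrays.

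For NDEP 3 genes differed, Chil4 by 2.75 log2, Rnase2a by 2.06 and Cd209e by 1.02. 9 of 100 splits of the arrays gave as many, with a highest other count of 9. For ADEP 3 genes differed, Ccl11 by 1.32, Timm10b by -0.80 and Bambi by -0.78. 2 of 100 splits gave as many and the highest other was 4, and 0 genes passed with heart and fat scores as covariates. For CDEP 46 genes differed, among them Chil4 by 3.54, Arg1 by 3.1, Cxcl9 by 2.87, Iigp1 by 2.45, Chil3 by 2.40, Ehd2 by -1.32, Rps4l by -1.07, Hamp by -1.02, Rraga by -0.91 and Tmem243 by -0.86. 5 of 100 splits gave as many. The highest other split called 120 genes, which points to a structure of the samples, since that split and each other as large kept all 6 or 0 of the OVA labels among the CDEP arrays and so the difference between those mice. For any particle the exchange of OVA labels can leave such differences in place, so these splits do not decide on chance.

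Heart muscle and fat genes were lower in CDEP_OVA than in OVA, by -0.73 ± 0.19 and -0.60 ± 0.26 log2 (list mean and SE). The heart list fell further than the endothelial (-0.138 ± 0.111) and alveolar type 1 lists (-0.049 ± 0.083). The difference was -0.617 ± 0.251 log2, over 2 SE as the test asked. A bound of 2 SE beyond 0.2 log2, used first and replaced after the value was seen, was not met. A variable heart share could give this too, so dilution of resident lung cells stays open. A variable share of heart muscle in the sampled tissue may contribute, since the 20 heart genes moved together within groups with a mean pairwise correlation of 0.533, against 0.0510 for the 95th percentile of random lists and a bound of 0.5 set beforehand. For fat the correlation over all 10 genes was 0.262 against 0.140, which leaves a share of fat open, but a first run limited to the 3 fat genes above a mean log2 level of 7 gave 0.0734, under the bound of 0.2 set beforehand as counting against it; that limit was not part of the stated test, was dropped after its value was seen, and for heart had given 0.568 over 15 genes. A change in the animals' own muscle or fat was not tested.

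The interferon response list mean rose over OVA by 1.09 ± 0.16 log2 in CDEP_OVA, with 15 members past the threshold, and by 0.439 ± 0.159 in NDEP_OVA. CDEP_OVA scores were uneven, at 1.01, 1.13 and 0.377, against -0.245 ± 0.077 in OVA. A single array is argued against, as at least 10 members passed with any 1 array left out. So is RNA quality, as 15 passed with its covariates and 602 genes in all. More T cells as carriers are argued against by a marker change of 0.0237 log2 (upper 95% limit 0.189), under 0.5 times the interferon change with any 1 array left out. More NK or cytotoxic cells stay open, as Gzmb rose and markers changed by 0.233 (upper limit 0.539). That limit was under 0.5 times the interferon change, but not without OVA replicates 1 or 2 or CDEP_OVA replicates 1 or 3. A response to CDEP with OVA stays open too, found and tested on the same arrays.

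Clca1 spread widely among the 3 OVA arrays, at 6.79, 3.80 and 9.29 log2. An exchange with a saline array stays open, as the second lowest OVA score of the mucus list lay only 0.0984 above the highest saline score, within the SD of 0.226 of the saline arrays. Noise of single probe sets is argued against, as the mucus list without Clca1 differed by a median of 0.478 between OVA arrays 3 and 2, at percentile 100 of 10000 random lists. A single wrong label or a failed exposure of the mouse of OVA array 2 could not be told apart from a mouse that did not respond, because its mucus score lay -0.596 from the highest saline array and 0.153 below the lowest. A difference between mice in the response to OVA stays open and was not tested.

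For comparisons of 3 with 3 arrays, the 10 possible splits are too few for a share under 0.05. The real counts and the highest of the other splits were 335 and 6 for NDEP, 205 and 0 for ADEP, 501 and 0 for CDEP and 0 and 0 for OVA, each against saline. Against OVA they were 257 and 1 for NDEP_OVA, 85 and 1 for ADEP_OVA and 594 and 0 for CDEP_OVA. Between particles they were 1 and 0 for ADEP and NDEP, 0 and 0 for CDEP and NDEP, and 0 and 1 for CDEP and ADEP. With OVA they were 2 and 3 for ADEP and NDEP, where 3 of 10 splits gave as many, 1 and 26 for CDEP and NDEP, where 4 did, and 177 and 0 for CDEP and ADEP, where 1 did. For the averaged OVA effect 1 of 100 splits, the real one, gave 306 genes and the highest other gave 74. That argues against chance for a difference between mice with and without OVA in at least 1 background. It does not show an effect of OVA without particles, where 0 genes passed.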

How the results depend on the processing

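The fits with heart and fat scores as covariates, with RNA quality covariates and without the 2 arrays of highest Gapdh difference, the list tests with 1 array left out and the fits with separate control arrays, were chosen only after results were seen. Counts are genes past the threshold, of particles over saline or of particle and OVA groups over OVA unless another group is named. No count moved by over 1.5 times with dim probe sets left out or with a trended robust variance, and every called gene kept its sign in each fit with 1 array left out. The number of arrays per group limits what can be detected, and signal over background was not analysed here. For changes other than fewer arrays the cause was not tested.

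With array weights the counts were 718 for NDEP, 718 for ADEP, 1450 for CDEP, 12 for OVA, 400 for NDEP_OVA, 313 for ADEP_OVA, 1055 for CDEP_OVA, 610 for the averaged OVA effect, 13 for NDEP interaction, 51 for ADEP interaction, 263 for CDEP interaction, 5 for ADEP_OVA over NDEP_OVA and 13 for CDEP_OVA over NDEP_OVA. With only the compared groups in the fit, and so fewer arrays to estimate the spread, the counts were 181 for NDEP, 111 for ADEP, 297 for CDEP, 102 for NDEP_OVA, 6 for NDEP interaction, 25 for CDEP interaction, 0 for ADEP over NDEP, 1 for CDEP over NDEP, 1 for ADEP_OVA over NDEP_OVA, 0 for CDEP_OVA over NDEP_OVA and 19 for CDEP_OVA over ADEP_OVA. With all probe sets the counts were 5 for NDEP interaction, 1 for ADEP interaction and 105 for CDEP interaction. With quantile normalization again the counts were 2 for CDEP_OVA over NDEP_OVA and 108 for CDEP_OVA over ADEP_OVA. With heart and fat covariates the counts were 166 for NDEP, 32 for ADEP, 280 for CDEP, 195 for ADEP_OVA, 385 for CDEP_OVA, 44 for the averaged OVA effect, 0 for ADEP interaction and 56 for CDEP_OVA over ADEP_OVA. There the correlation of CDEP fold changes without and with OVA was 0.537, 25 genes were shared by all 3 particles against saline and 107 with OVA, where the main values were 0.424, 103 and 56. Without the 2 arrays of highest Gapdh difference, saline replicate 1 and CDEP_OVA replicate 3, the counts were 189 for NDEP, 33 for ADEP, 173 for CDEP, 1 for OVA, 143 for ADEP_OVA, 7 for NDEP interaction, 2 for ADEP over NDEP, 33 for CDEP_OVA over NDEP_OVA and 115 for CDEP_OVA over ADEP_OVA. With RNA quality covariates the counts were 126 for NDEP, 3 for CDEP, 130 for ADEP_OVA, 1 for NDEP interaction, 11 for ADEP interaction, 13 for CDEP interaction, 0 for ADEP over NDEP and 9 for CDEP_OVA over NDEP_OVA. With a different control array for each particle, and so 1 in place of 3, the genes shared by all 3 particles fell to a median of 3 over 6 assignments against saline and of 2 with OVA.

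With 1 array left out the counts ran from 152 to 407 for NDEP, 8 to 274 for ADEP, 144 to 603 for CDEP, 0 to 1 for OVA, 78 to 423 for NDEP_OVA, 18 to 97 for ADEP_OVA, 217 to 573 for CDEP_OVA, 224 to 439 for the averaged OVA effect, 2 to 6 for NDEP interaction, 1 to 19 for ADEP interaction, 17 to 73 for CDEP interaction, 0 to 1 for ADEP over NDEP, 0 to 0 for CDEP over NDEP, 0 to 0 for CDEP over ADEP, 1 to 6 for ADEP_OVA over NDEP_OVA, 1 to 30 for CDEP_OVA over NDEP_OVA and 35 to 386 for CDEP_OVA over ADEP_OVA. The correlations of fold changes without and with OVA ran from 0.457 to 0.528 for NDEP, 0.189 to 0.376 for ADEP and 0.341 to 0.506 for CDEP.

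With the replicate number as a replicate block the counts were 7 for NDEP interaction, 4 for ADEP_OVA over NDEP_OVA and 6 for CDEP_OVA over NDEP_OVA. It moved no other count by over 1.5 times. Arrays with the same number had a mean correlation of 0.0312 over 84 pairs, from -0.323 to 0.354, with 27 over 0.1, and 10 of 24 arrays correlated best with their own number, so the numbers were not taken as pairs.

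List directions reversed in 12 cases, given as signed -log10 p. With heart and fat scores as covariates these were interferon response genes for NDEP at -0.175, acute phase proteins (2.89), ciliated cell genes (0.648) and extracellular matrix genes (-0.193) in the ADEP interaction, and ciliated cell genes for CDEP over ADEP at 0.130. With RNA quality covariates they were interferon response genes for CDEP at -0.00524, alveolar type 1 genes in the NDEP and CDEP interactions at 0.120 and 0.0264, and ciliated cell genes for CDEP over ADEP at 0.674. With 1 array left out, 164 of 279 list calls held in every fit, and values ran from -5.05 to 0.337 for heart muscle genes after OVA (reversed without saline replicate 3), from -0.112 to 6.17 for endothelial genes in ADEP_OVA over NDEP_OVA (without ADEP_OVA replicate 1) and from -15.9 to 0.00279 for alveolar macrophage genes in CDEP_OVA over NDEP_OVA (without NDEP_OVA replicate 3). With an estimated correlation 34 of 279 list calls kept their side of the threshold and 245 lost it.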

Other observations

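The lists and comparisons here were fixed before the data were examined. Which of them to give was decided after the results were seen, and so were the other values, the covariate fits and the list tests with 1 array left out. Complement components were higher in NDEP_OVA than in OVA, median 0.64: 5 rose and 0 fell of 7, 5 and 0 adjusted over the list alone (camera adjusted p = 3.85e-06, adjusted p = 0.0229 with an estimated correlation). That median was 0.33 without NDEP_OVA replicate 3. MHC class II genes did the same, median 0.55, with list scores of 0.003, 0.289 and 0.630: 5 rose and 0 fell of 9, 8 and 0 adjusted over the list alone (camera adjusted p = 5.22e-10, or 0.0328 with an estimated correlation). For unfolded protein response genes in that comparison, 4 rose and 0 fell of 15, 8 and 0 adjusted over the list alone (camera adjusted p = 2.63e-09, adjusted p = 0.0229 with an estimated correlation). Cell cycle genes in CDEP_OVA against OVA gave 4 rose and 0 fell of 24, 9 and 0 adjusted over the list alone (camera adjusted p = 9.56e-05, adjusted p = 0.152 with an estimated correlation), with a median of 0.19.

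Some lists were called only in comparisons between particles or in interactions. T cell markers differed between CDEP and NDEP, median -0.09 (camera adjusted p = 0.0316, adjusted p = 0.824 with an estimated correlation). The call was lost without NDEP replicate 1 or CDEP replicates 2 or 3. B cell and plasma cell markers differed between ADEP_OVA and NDEP_OVA, median -0.24 (camera adjusted p = 0.0153, adjusted p = 0.610 with an estimated correlation). The median was -0.37 without NDEP_OVA replicate 1, and the call was lost without NDEP_OVA replicates 2 (-0.10) or 3 (-0.10) or ADEP_OVA replicate 1 (-0.13). Skeletal muscle genes differed between CDEP_OVA and NDEP_OVA, median -0.24 (camera adjusted p = 2.49e-05, adjusted p = 0.236 with an estimated correlation). Without NDEP_OVA replicate 2 the median was -0.11 with no call, and without NDEP_OVA replicate 1 it was -0.40. The aryl hydrocarbon receptor targets were called in the NDEP by OVA interaction, median -0.19 (camera adjusted p = 0.0459, adjusted p = 0.250 with an estimated correlation). They were not called without OVA replicate 3 or replicates 2 or 3 of NDEP_OVA, saline or NDEP. Ciliated cell genes differed between CDEP and ADEP, median -0.22 (camera adjusted p = 0.00926, adjusted p = 0.582 with an estimated correlation). Their direction reversed with heart and fat scores and with RNA quality covariates, the median was -0.34 without ADEP replicate 2, and the call was lost without ADEP replicates 1 or 3.

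Xist, the transcript that silences an X chromosome, lay at 8.84 log2 in CDEP_OVA replicate 2 and between 10.3 and 10.9 on the other arrays, and all mice are labelled female. Among 2246 probe sets without a single gene symbol, 52 were higher and 39 lower with CDEP than with saline, 36 and 17 with CDEP_OVA than with OVA, and 23 and 56 for the averaged OVA effect. The first principal component over all genes held 22.1% of the variance, and the next ones 15.3% and 9.54%.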
